A study of Ovis aries with 10 samples.

How the data were processed

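The series measured RNA of lambs on 2-colour cDNA microarrays, with 1 hair lamb and 1 wool lamb of the same infection status and day of sampling on each array. Per the labels, 2 tissues were taken, the abomasum (the acid-secreting stomach compartment in which the blood-feeding nematode Haemonchus contortus lives) and the abomasal lymph node. Abomasal RNA was extracted with TRIzol and lymph node RNA with RNeasy columns, per the labels' protocols. Each of the 10 samples stands for 1 tissue, infection status and day and holds 3 or 6 arrays, and the series' design names the lamb pair as the experimental unit, so the array was the replicate here. There were 24 arrays per tissue, with 6 for infected day 3, 6 for infected day 27 and 12 for uninfected controls killed on 3 days.

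Per the labels, the authors found the spots with MolecularWare DigitalGENOME Pro and marked spots of abnormal shape, saturated intensity or array defects. Per the file headers, the deposited scanner files give for each spot the mean pixel intensity in channels A and B and the median intensity of the local background, in separate columns. They were treated as raw. For 1 lymph node array, replicate 6 of infected day 3, the deposited file gives total spot intensities for Cy3 and Cy5 and no background, and these totals were divided by 419, the median number of pixels per spot on the other lymph node arrays. The files do not say which dye channel A is. It was taken as Cy3 from that 1 array: over spots, its raw log ratio of Cy5 over Cy3 had a positive Spearman correlation with that of channel B over A on 21 of the other 23 lymph node arrays (median 0.667, lowest -0.588), a comparison chosen after seeing the data. The same order of channels was assumed for the abomasum, where it was not tested. The deposited value tables, 1 per tissue, hold 1 log ratio per probe and sample and were treated as a score, because the sources used here give neither the base of the logarithm nor the direction. Their medians lay between -0.0046 and 0.0017 for the abomasum and between -0.0045 and 0.00066 for the lymph node, so the columns are centred near 0. Their SD was 0.833 to 1.31 times that of the log2 ratios of the scanner files without background correction for the abomasum and 0.634 to 0.995 times for the lymph node, which leaves the base open.

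The dye carried by each breed came from the array file names, since the labels give both dyes for both breeds. With that reading the groups of 6 arrays held 3 arrays of each orientation and the groups of 3 held 2 and 1, the balance that the series' design describes. The direction of hair over wool is therefore given as likely for the lymph node and as assumed for the abomasum. For the lymph node the direction rests on the file names and on the match of the channels, with the limit given above. The authors' values, whose direction is not given in the sources used here, do not settle it, and 4 of the 24 lymph node arrays correlated with them below 0. Among these was the array that names its dyes, replicate 6 of infected day 3, at -0.32.

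Intensities were background-corrected by the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, and the log2 ratio of Cy5 over Cy3 was normalised within each array by loess with a span of 0.3 and 4 iterations. Spots that the authors had marked as bad (1.06% of abomasum spots and 1.46% of lymph node spots), blank, negative and Lambda Q spots were left out, the spots of a probe were averaged, and control gene spots had no weight in the loess curve. The abomasum array has 19200 spots and 18265 probes. The lymph node array has 3888 spots and 1369 probes, most of them printed on 2 spots. Probes with a usable spot on at least 4 of the 6 arrays of each infected group and 8 of the 12 control arrays were tested, which left 18247 abomasum probes and 1368 lymph node probes. Lymph node clone names stand in the file of 1 array and were carried to the others by spot order. The median GAPDH spot lay above the median blank spot on each of the 24 arrays in both dyes. This is a weak check of the order, since a median of 60.7% of all spots exceeded even the 95th percentile of the blank spots in Cy3.

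For each tissue, limma's linear model held the hair over wool log2 ratio of the 5 groups of arrays, signed by dye orientation, and a dye effect for each probe, with moderated variances. Each comparison was fitted as a coefficient of its own, so that standard errors are exact where values are missing. The breed difference was taken over all arrays, in each infected group and in the controls, and its change from the controls to each infected group was tested as a difference of differences. The infection comparison used the mean log2 intensity of both dyes on an array after quantile normalisation between arrays, and so compares different slides. All tests were 2-sided with Benjamini-Hochberg adjustment over the probes of a tissue and a threshold of 0.05, in 16 comparisons in all. Arrays have no sequencing depth. Their number limits the precision, and so does the signal over background.

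The files name probes by EST accession (abomasum) or clone (lymph node). None of 18263 abomasum IDs and none of 1366 lymph node IDs matched the sheep gene table used for names (ARS-UI_Ramb_v3.0), so no gene names other than those of the control genes GAPDH, beta-actin and, on the lymph node array, RPL19 could be given. The 28 gene lists and cell type markers fixed before the data were examined were not tested, because 1 of the 3 named genes is a member of any list. The rule for named genes (the largest changes past the threshold and a fixed set of cytokine and immunoglobulin genes) was limited for the same reason to the control genes. The 3 probes past the threshold are given by their IDs and were chosen after their values were seen. No per-sample column was left unassigned.

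The model was tested on simulated data, made from the residuals of the probes measured on each array by multiplying whole arrays by 1 or -1 at random and adding known changes to 200 probes, in 3 simulations per comparison. With 200 probes changed at once, the adjusted threshold is easier to pass than with few changes. The changes were added after normalisation, so any loss of signal near background was not simulated. The shares called may therefore be too high for the real data. The alternatives chosen before the data were examined were no background correction, median centring instead of loess or quantile normalisation, bad spots kept, the dimmest 25% of probes left out, the date as a block, no dye effect, the arrays of the compared groups alone, control day 27 alone, and each array left out in turn. Array quality weights, print-tip loess over the 48 printed blocks, a filter on probes above blank spots (spots above the 95th percentile of the blank spots in both dyes on at least 50% of arrays, averaged over the spots of a probe) and an exchange of the breeds on 2 lymph node arrays were added after seeing the data. Scan or file dates (3 per tissue, with 1 lymph node array undated) served as batches.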

Results

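Gene expression was measured in the abomasum and the abomasal lymph node of hair lambs, of mostly St. Croix ancestry, and of wool lambs from a composite of Dorset, Rambouillet and Finnsheep breeding. All lambs had been drenched weekly with 3000 infective larvae of Haemonchus contortus for 4 weeks before the study, so the comparison concerned animals with prior exposure. Infected lambs were killed on day 3 or on day 27, days chosen for the response to larvae and to adult worms, and control lambs on days 17, 27 and 38. No control was killed on day 3, so wherever infected day 3 is set against controls, infection and day of sampling cannot be told apart. Each array carried 1 hair and 1 wool lamb. There were 24 arrays per tissue, 6 for each infected day and 12 for controls (3, 6 and 3 by day). The direction of hair over wool was likely for the lymph node and assumed for the abomasum, being taken from the array file names and the order of the dye channels.

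Abomasum probes were brighter against the blank spots than lymph node clones, mainly in Cy5. In the abomasum, a median of 61.4% of spots per array exceeded the 95th percentile of the blank spots in Cy3 (range 43.7 to 81.6%, n = 24 arrays) and 59.2% in Cy5 (36.4 to 79.5%). In the lymph node the median was 60.7% in Cy3 (39.6 to 79.9%) and 38.1% in Cy5 (6.35 to 80.2%), and 9 of the 24 arrays lay under 20% in Cy5. Among these 9 was infected day 3 replicate 6 (14.9%), whose share rests on intensities from which no background could be subtracted. The median spot intensity of an array was divided by the median local background of that array. The median of this ratio over arrays was 1.15 in Cy3 and 1.16 in Cy5 in the abomasum. In the lymph node it was 1.09 and 1.04, without the 1 array that has no background. In the abomasum the median spot of GAPDH, an enzyme of glycolysis, and of beta-actin exceeded the 95th percentile of the blank spots on 24 of 24 arrays in both dyes. Lymph node GAPDH did so on 24 arrays in Cy3 and 13 in Cy5, beta-actin on 20 and 2, and RPL19 on 11 and 2. In lymph node Cy5, beta-actin and RPL19 each lay above the median of the blank spots on 21 of 24 arrays, so their lymph node ratios come from spots near background.

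**Figure D1:**
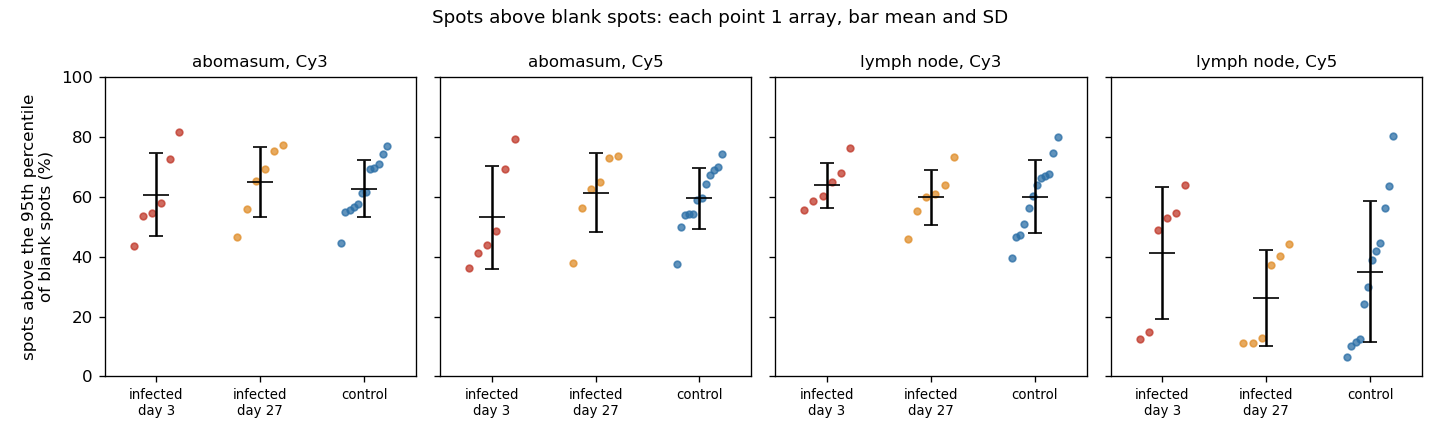
Percent of spots above the 95th percentile of the blank spots (y axis) in 3 groups of arrays (x axis), per tissue and dye. Points are arrays and bars give the mean and SD. Lymph node Cy5 values reach down to 6.35%, while abomasum Cy5 values start at 36.4%. For lymph node infected day 3 replicate 6 no background was subtracted.

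The first question was whether the breeds differed in the abomasum, over all arrays and within each status. GAPDH and beta-actin, a protein of the cytoskeleton, differed little between hair and wool lambs. Over all arrays the log2 ratio of hair over wool was -0.014 ± 0.046 (SE, 24 arrays) for GAPDH and -0.0094 ± 0.047 for beta-actin, and both signs turned without background correction and with median centring. GAPDH was at -0.038 ± 0.13 (SD, n = 6) on infected day 3, -0.031 ± 0.086 (SD, n = 6) on infected day 27 and 0.025 ± 0.061 (SD, n = 12) in controls. Beta-actin was at -0.023 ± 0.091, -0.042 ± 0.13 and 0.037 ± 0.082 in the same groups. The 95% interval of the GAPDH ratio over all arrays ran from -0.11 to 0.081 and that of beta-actin from -0.11 to 0.087.

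**Figure D2:**
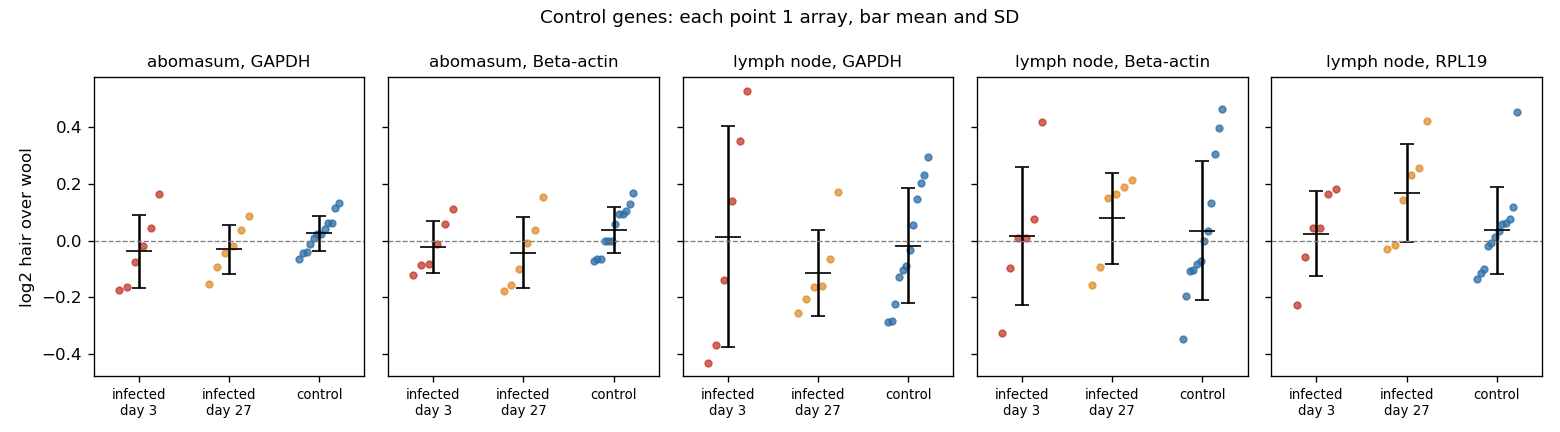
Log2 ratio of hair over wool (y axis) of the control genes in 3 groups of arrays (x axis), after removal of the dye effect. Points are arrays and bars give the mean and SD, with 6, 6 and 12 arrays per group. Abomasum GAPDH averages -0.038, -0.031 and 0.025.

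Of 18247 abomasum probes, 0 passed the threshold in limma over all arrays, and 973 had an unadjusted p under 0.05 where chance gives 912. The same test called 0 probes on infected day 3 (1374 at an unadjusted p under 0.05), 0 on infected day 27 (400) and 0 in controls (806). The 95% interval of the breed difference lay within 2-fold for 99.9% of probes over all arrays, 91.2% on infected day 3, 95.1% on infected day 27 and 99.3% in controls. These intervals concern measured ratios, those of spots near background included, and need not bound the difference in RNA. In simulated data on 14962 probes, 71.3% of 1.41-fold and 100% of 2-fold breed differences over all arrays were called. On infected day 3 the simulated shares were 21.3% and 70.0%, and 15.5% of the calls were false, against 1.13% on infected day 27. Within each of the 3 scan dates, of 4, 12 and 8 arrays, limma called 0 probes, with 1959, 815 and 969 at an unadjusted p under 0.05. The 1959 thus rest on 4 arrays, and the dates are not comparable in size.

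The next question was whether the breed difference in the abomasum changed with infection. GAPDH changed by -0.063 ± 0.11 (SE) from control to infected day 3 and by -0.056 ± 0.11 from control to infected day 27, and beta-actin by -0.059 ± 0.11 and -0.079 ± 0.11. For infected day 3 minus control limma called 0 probes, with 1071 at an unadjusted p under 0.05. For infected day 27 minus control it called 0, with 438 at that level. The median 95% half-width was 0.52 on the log2 scale in both comparisons. In simulated data, 56.0% and 54.0% of 2-fold changes were called, and 12.5% and 2.18% of the calls were false.

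Infected and control lambs were then compared across arrays, with both breeds together. In the abomasum 2 probes, the ESTs BE481083 and AW655214, were lower on infected day 3 than in controls, none of which was killed on day 3. BE481083 fell by 3.24 on the log2 scale (SE 0.55, 9.47-fold), from a mean log2 intensity of 11.35 ± 0.98 (SD, n = 11) in controls to 8.11 ± 1.54 (SD, n = 6), and 5 of the 6 infected day 3 arrays lay below the lowest control array. AW655214 fell by 2.51 (SE 0.45, 5.69-fold), from 10.71 ± 0.77 (SD, n = 12) to 8.20 ± 0.92 (SD, n = 6), also with 5 of 6 arrays below the lowest control. The limma adjusted p was 0.0473 for both. On infected day 3, BE481083 lay above the blank spots on 1 of 6 arrays in Cy3 and 2 in Cy5 and AW655214 on 1 in each dye, so the sizes of both falls rest on spots near background, and across the other settings the log2 difference ran from -3.50 to -0.54 for BE481083 and from -2.60 to -0.39 for AW655214, smallest in size without background correction. With each array left out in turn it ran from -3.71 to -2.90 and from -2.79 to -2.27. On infected day 27 the means were 11.41 ± 1.19 for BE481083 and 10.79 ± 1.26 for AW655214. GAPDH differed between infected day 3 and control by -0.16 ± 0.21 (SE) and beta-actin by -0.045 ± 0.23, with limma adjusted p of 0.882 and 0.979.

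Neither call held with the scan date as a block, where BE481083 was lower by a log2 value of -2.78 (SE 0.62, limma adjusted p = 0.595) and AW655214 by -2.47 (SE 0.47, adjusted p = 0.281), over a range of adjusted p from 0.028 to 0.595 and from 0.028 to 0.484 across the settings tried, and from 0.0038 to 0.236 and from 0.0088 to 0.236 with each array left out. Within the scan date that held 4 infected day 3 and 5 control arrays the log2 differences were -2.06 (SE 0.73) and -2.07 (SE 0.55). There limma called 0 probes, with 588 at an unadjusted p under 0.05. Within the date with 2 infected day 3 arrays and 1 control array the differences were -2.99 and -4.42. With single arrays left out, the count of called probes ranged from 0 to 4. Month marks in the abomasum file names, whose meaning is not given in the sources used here, were not shared by infected and control arrays, so whatever they stand for and infection cannot be told apart. The infected day 3 comparison had 1494 probes at an unadjusted p under 0.05, of which 749 were higher. For infected day 27 limma called 0 probes, with 707 at that level, and GAPDH and beta-actin differed from control by -0.097 ± 0.21 and 0.15 ± 0.23 (SE). In simulated data 72.7% of 4-fold and 8% of 2-fold changes on infected day 3 were called, and 8.67% of the calls were false, above the 5% aimed at.

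**Figure D3:**
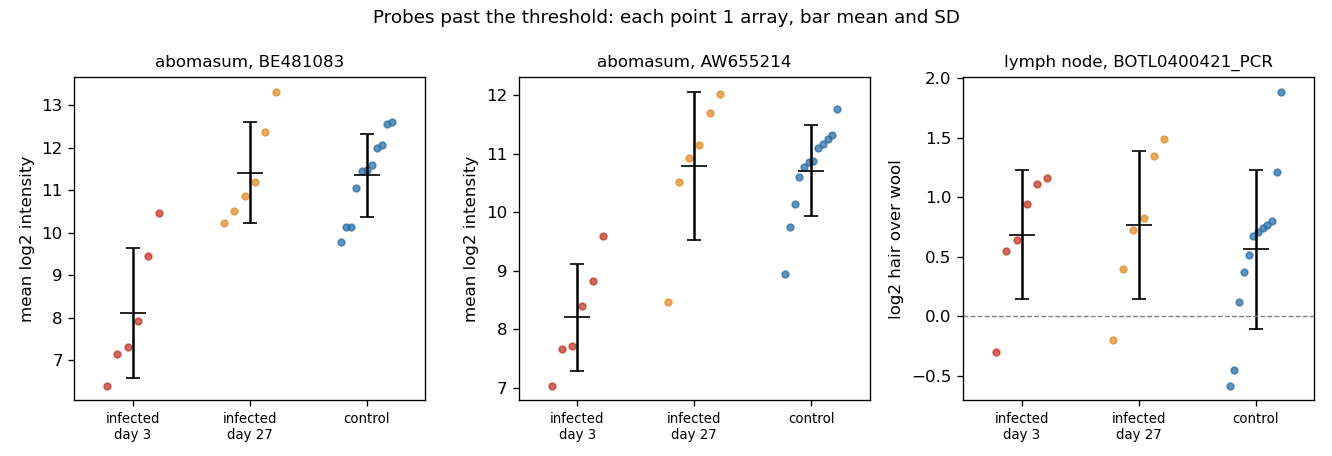
Values per array (y axis) of the 3 probes past the threshold in 3 groups of arrays (x axis), as mean log2 intensity of both dyes for BE481083 and AW655214 and as log2 ratio of hair over wool for BOTL0400421_PCR. Points are arrays and bars give the mean and SD. BE481083 averages 8.11 on infected day 3 and 11.35 in controls.

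In the lymph node, the same breed comparisons were made with 1368 clones. The clone BOTL0400421_PCR was likely higher in hair lambs, with a log2 ratio of 0.67 (SE 0.13, 1.59-fold, limma adjusted p = 0.00703) and hair above wool on 20 of 24 arrays. At least 1 of its 2 spots lay above the 95th percentile of the blank spots on 24 of 24 arrays in Cy3 and 14 in Cy5, so the size of the ratio is uncertain, and across the alternatives it ran from 0.067 to 0.81. Infected day 3 arrays 1 and 6, counted among the 20, opposed the authors' values (correlation across probes -0.17 and -0.32), and with the breeds exchanged on both the ratio was 0.50 (SE 0.14, limma adjusted p = 0.219) and the call was lost. Infected day 3 array 5 and control day 27 array 5, which opposed the match of the channels, were also among the 20 (log2 ratios 1.16 and 0.80). An exchange of breeds on these was not tested. Its ratio was 0.69 ± 0.54 (SD, n = 6) on infected day 3, 0.76 ± 0.62 (SD, n = 6) on infected day 27 and 0.56 ± 0.67 (SD, n = 12) in controls. The control days differed. The 3 arrays of control day 38 were at -0.45, -0.58 and 0.37. Arrays of control day 17 ran from 0.12 to 1.21 and those of control day 27 from 0.68 to 1.89. GAPDH was at -0.039 ± 0.11 (SE, 24 arrays), beta-actin at 0.043 ± 0.11 and RPL19, a protein of the large ribosomal subunit, at 0.076 ± 0.11 over all arrays. The sign of beta-actin turned without background correction, with median centring and with the date as a block. In controls GAPDH was at -0.018 ± 0.20, beta-actin at 0.035 ± 0.25 and RPL19 at 0.036 ± 0.15 (SD, n = 12). On infected day 27 RPL19 was at 0.17 ± 0.17 and GAPDH at -0.11 ± 0.15 (SD, n = 6), and on infected day 3 they were at 0.025 ± 0.15 and 0.013 ± 0.39.

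The call of BOTL0400421_PCR was lost without background correction (log2 ratio 0.067, limma adjusted p = 0.999), with median centring (0.45, adjusted p = 0.654) and without the dye effect (0.67, adjusted p = 0.283), over a range of adjusted p from 0.00018 to 0.999 across the alternatives. Within the 3 file dates, of 6, 6 and 11 arrays, its ratio was 0.95 (SE 0.30), 0.25 (SE 0.21) and 0.96 (SE 0.21). The limma adjusted p was 0.330, 0.902 and 0.101. The date at 0.25 held all 3 arrays of control day 38, so that date and that control day cannot be told apart. The counts of called clones within these dates were 2, 0 and 0, with 149, 58 and 98 at an unadjusted p under 0.05. Over all arrays 1 clone was called and 76 had an unadjusted p under 0.05, against 68 by chance. Limma called 0 clones on infected day 3 (33 at that level), 0 on infected day 27 (93) and 0 in controls (63). The count of 33 takes the breeds of infected day 3 arrays 1 and 6 from the file names. Exchanges of breeds within the infected day 3 pairs gave a median of 55 (highest 156). The 95% interval of the breed difference lay within 2-fold for 100% of clones over all arrays, 95.8% on infected day 3, 88.8% on infected day 27 and 99.9% in controls. These intervals concern measured ratios. In Cy5, 9 of the 24 arrays had under 20% of spots above blank spots, so the intervals need not bound the difference in RNA. In simulated data on 1343 clones, of which 200 were changed, 78.0% of 1.41-fold and 100% of 2-fold breed differences over all arrays were called. These shares may be lower where few clones change. Of the simulated calls, 7.05% were false over all arrays, 16.5% on infected day 3, 6.34% on infected day 27 and 9.01% in controls, above the 5% aimed at.

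The breed difference in the lymph node showed no called change with infection. RPL19 changed by -0.011 ± 0.25 (SE) from control to infected day 3 and by 0.13 ± 0.25 to infected day 27, GAPDH by 0.032 ± 0.26 and -0.095 ± 0.26, and beta-actin by -0.020 ± 0.26 and 0.043 ± 0.26. Limma called 0 clones for infected day 3 minus control, with 41 at an unadjusted p under 0.05, and 0 for infected day 27 minus control, with 79. The infected day 3 count rests on the file names for the breeds of arrays 1 and 6, which opposed the authors' values. In simulated data, 56.0% and 58.0% of 2-fold changes were called.

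Between infected and control lymph nodes, with both breeds together, RPL19 differed by 0.015 ± 0.14 (SE) on infected day 3 and -0.12 ± 0.14 on infected day 27. GAPDH differed by 0.072 ± 0.17 and -0.072 ± 0.17, and beta-actin by 0.26 ± 0.22 and 0.037 ± 0.22. Limma called 0 clones on either day, with 48 and 71 at an unadjusted p under 0.05. With each array left out in turn these counts ranged from 40 to 101 and from 44 to 87. In simulated data 76.0% and 76.7% of 2-fold changes were called.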

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

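In 36 groups of arrays tested for an array far from the rest, 1 array stood apart, and chance gives about 2. On replicate 1 of lymph node control day 27, the clone BOTL0400421_PCR had a log2 ratio of hair over wool of 1.89, while the other 5 arrays lay between 0.68 and 0.80. The limma adjusted p of the clone stayed between 0.0013 and 0.042 when each of the 24 arrays was left out in turn.

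Spots named Lambda Q, which no comparison used, were brighter than the blank spots. In the abomasum a median of 97.5% of them per array exceeded the 95th percentile of the blank spots in Cy3 and 97.5% in Cy5, on 24 of 24 arrays above the 5% that blank spots themselves give. In the lymph node the medians were 54.2% in Cy3 and 10.9% in Cy5, above 5% on 22 and 21 of 24 arrays. Spots named Negative on the abomasum array were at 6.71% in Cy3 and 6.60% in Cy5. What Lambda Q spots hold is not given in the sources used here, and no explanation was tested.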

How the results depend on the processing

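Array quality weights, print-tip loess, the filter on probes above blank spots and the exchange of breeds on 2 arrays were chosen after seeing the data. Of 16 counts of called probes, 14 were 0, and these stayed at 0 in every alternative run for them and with each of the 24 arrays left out. For infected day 3 minus control in the abomasum, the count of 2 became 0 without background correction, with bad spots kept, with the date as a block, with control day 27 alone and with array quality weights. It was 3 among probes above blank spots in both dyes, and 2 with arrays centred on their median and with the dimmest 25% of probes left out. With single arrays left out it ranged from 0 to 4, with 0 in 14 of 24 fits. It was 4 without infected day 27 replicate 3 or control day 38 replicate 1, 3 without infected day 3 replicate 1 or infected day 27 replicate 2, 2 without infected day 27 replicate 4, control day 17 replicate 3 or control day 27 replicate 5, 1 without infected day 3 replicate 3 or 4 or control day 27 replicate 6, and 0 without any other array. For the breed difference over all lymph node arrays, the count of 1 became 0 without background correction, with median centring, without the dye effect, with the breeds exchanged on infected day 3 arrays 1 and 6 and among the 419 clones whose spots, on average, lay above blank spots in both dyes on at least 50% of arrays, which do not include BOTL0400421_PCR. It became 2 with print-tip loess, and stayed 1 with each array left out. Apart from the clone missing from the 419, the cause was not tested.

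Control gene ratios near 0 changed sign, none past the threshold. Abomasum GAPDH was at 0.0046 without background correction and 0.0083 with median centring, and beta-actin at 0.0012 and 0.015. Lymph node beta-actin was at -0.0055 without background correction, -0.011 with median centring and -0.023 with the date as a block. Signal over background is a limit in the lymph node, with a median Cy5 spot intensity at 1.04 times the median background of the array. Camera with an estimated correlation was not run, since no gene list could be tested, and the authors' values have no replicate spread, so they give correlations and no count. The breed comparison is already paired, since each array sets 1 lamb pair side by side. No pairing between infected and control groups was possible, because the labels give no number shared between groups.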

Other observations

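The tests of moved rows in the authors' tables and the array quality weights were chosen after the result was seen, and the probes used for the exchanges of breeds and labels were settled after a first run. Breed differences of separate groups were compared across probes, which are not independent replicates. In the abomasum (14962 probes measured on each array) the correlation across probes was 0.051 between infected day 3 and control, 0.046 between infected day 27 and control and 0.016 between both infected days, and 7, 4 and 38 of 100 random exchanges of breeds within pairs gave a value as high. In the lymph node the correlations were 0.056, 0.013 and -0.019, with 31, 42 and 62 of 100. Dye had a larger part in the ratios than breed. In the abomasum 2419 probes differed between dyes past the threshold of limma, 805 of them higher in Cy5 and 1614 in Cy3, and in the lymph node 355 (157 and 198).

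Abomasum breed differences had 1374 probes at an unadjusted p under 0.05 on infected day 3 and 400 on infected day 27, with 912 given by chance. The order turned without background correction (787 and 938) and with the arrays of the compared group alone (705 and 737). Noisy arrays may account for the excess on day 3, since with array quality weights the counts were 869, which is 0.952 times chance, and 834. From the dimmest to the brightest 25% of probes the share at this level was 7.61%, 8.92%, 9.08% and 4.51% (dimmest over brightest 1.68), with no steady rise toward background, and a part of spots near background stays open. A biological change of the breed difference by infection was tested as a difference of differences, for which limma called 0 probes, with 1071 at an unadjusted p under 0.05.

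In the lymph node the SD of the log ratio between spots of a clone ran from 0.246 to 1.09 over 24 arrays, with a median of 0.828. Weak Cy5 signal is a candidate explanation. The share of spots above blank spots in Cy5 correlated with this SD at Spearman's rho -0.870 and Pearson's r -0.848 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give, and 1e-05 after adjustment over both). Without the 2 arrays farthest from the median share, r was -0.810. Within the 3 file dates rho was -0.829 (6 arrays), -0.600 (6 arrays) and -0.791 (11 arrays). No biological explanation was tested.

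The authors' deposited table for the lymph node, in the order of the sorted clone names, correlated across probes with the scanner files at 0.422 to 0.754 over its 5 columns. Single arrays of infected day 3 ran from -0.318 to 0.490, with replicates 1 and 6 below 0. In the authors' deposited table for the abomasum, in the order of plate positions, the correlation was 0.684 for infected day 27 and 0.098, 0.0036, 0.230 and 0.035 for infected day 3, control day 17, control day 27 and control day 38. Rows may have moved in some columns, because the correlation passed 0.3 at some shift in 100% of windows of 1000 rows for infected day 3 (a shift of 1 row throughout), 91.7% for control day 27 (0 to 10 rows) and 75% for control day 38 (9 to 276 rows). For control day 17, which had 474 missing values, it did so in 0% of windows within 800 rows either way (highest 0.193). A shift that changes within a window could be missed, so a move of rows in that column stays open.

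Whether chance could give the counts was checked by exchanging breeds within pairs, or group labels between arrays, on the 14962 abomasum probes measured on each array and on 1368 lymph node clones. For probes at an unadjusted p under 0.05 in the abomasum, the breed difference had 802 over all arrays (31 of 100 splits as high, highest other 1156), 1115 on infected day 3 (21 of 32, 1774), 308 on infected day 27 (27 of 32, 487) and 667 in controls (85 of 100, 1050), and its change had 865 for day 3 (45 of 100, 1667) and 344 for day 27 (100 of 100, 1002). Chance was not excluded for any of these, nor for infected day 27 minus control with 576 (45 of 100, 1957). Infected day 3 minus control had 1159 such probes (4 of 100, 1693) and, over all 18247 probes, 2 calls (3 of 100, 4). Each share is under 0.05 taken singly, but labels were exchanged across scan dates, and 1 of the 3 dates held 6 control arrays and 0 of infected day 3. With the date as a block limma called 0 probes, with 1106 at an unadjusted p under 0.05. Within the date that held 4 infected day 3 and 5 control arrays 588 probes were at that level, below the 912 given by chance. The other date with both groups held 1 control array, too few for a count. The date therefore stays open as a source of the counts for infected day 3 minus control.

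In the lymph node the breed difference had 76 over all arrays (15 of 100 splits as high, highest other 130), 33 on infected day 3 (32 of 32, 156), 93 on infected day 27 (3 of 32, 97) and 63 in controls (55 of 100, 119), and its change had 41 for day 3 (90 of 100, 162) and 79 for day 27 (27 of 100, 150). Infected minus control had 48 for day 3 (57 of 100, 258) and 71 for day 27 (24 of 100, 160). Chance was excluded for none of these. For the 1 clone called over all arrays, 2 of 100 splits, the real one included, gave 1 call and none gave more, a share under 0.05 taken singly. Of the 18 checks of counts in both tissues 3 were under 0.05. The exchanges made for the correlations across probes, with 4 of 100 for infected day 27 and control in the abomasum, are not among the 18. The checks of calls were made only for comparisons that had calls, and infected day 3 minus control in the abomasum entered with both its checks. The 0.9 that 18 separate checks would give by chance is therefore not a fair expectation. The shares were not adjusted for the number of checks.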
